A study of Homo sapiens with 4 samples.

How the data were processed

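CTCF ChIP-seq was performed in MCF7 cells in normal and in glucose-free medium with 1 antibody, and 2 samples were recorded for each medium. Per the labels' protocols, sonicated chromatin was precipitated with a CTCF antibody and libraries were made with an Illumina ChIP kit. Bowtie2, deepTools 3.0 and the build hg19 are named in the submitters' processing notes. The peak names in the deposited files carry the name of the MACS peak caller. Its version, its settings, the use of an input control and any pooling of samples are not given in the sources used here.

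Each deposited file lists intervals with a chromosome, start, end, peak name and score. The score is the authors' own value per peak from the peak caller. It ends at a ceiling of 3100, as the scaled negative logarithm of a p-value written by early MACS versions does, but no header in the deposited files states this. A score depends on the depth of its library and was used mainly to rank and filter peaks within a list. Median scores of shared peaks are also given for each list. In the closing section, shared pairs were ranked within each list over the same 9806 sites. The lists hold no read counts, so depth is unknown, and no count model could be used. Starts were converted to 1-based positions.

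Samples were grouped by their titles. The 2 files of each medium were identical byte for byte, so each medium entered as 1 list, and each comparison describes 2 lists without replicate error. The replicate numbers 1 and 2 could pair samples, but both pairs hold the same values.

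Overlaps were computed with bedtools 2.31.1, and a peak was called shared when it overlapped a peak of the other medium by at least 1 bp. Shares have 95% exact (Clopper-Pearson) binomial intervals, and a share of 0 in a list is given with the upper end of that interval, for the score deciles also with 3 counts of the total. These cover counting error only. Scores were cut into deciles within each list. For chromosomes, windows of 1 Mb (by peak centre) and neighbours, the medium-only status of peaks was redrawn 10000 times within score deciles (for neighbours, within score deciles of each chromosome), and the range from the 2.5 to the 97.5 percentile of the draws is given. Chromosomes with fewer than 10 peaks in a list were left out of these counts. The running number in each peak's name was used to count unlisted peaks: numbers rise along each chromosome in both lists, and a medium-only peak had no number left when its neighbours in the other list had consecutive numbers. Some lines may be missing for reasons other than the authors' filter, so these numbers are called unlisted. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

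The code was checked on simulated data made from the 11415 normal-medium intervals and a copy of them. With 200 peaks removed and 300 kept in the numbering but unlisted, all 500 were found (100%) and 0 others. Of the removed peaks, 95.5% had no number left, and of the unlisted ones 0. Peaks were removed or unlisted at random, without regard to score. The real lists lacked more numbers, 2096 in normal medium and 1653 in glucose-free medium. Without any effect 5.04% of chromosomes fell outside the draws, and a doubled rate on chromosome 19 was found in 100% of simulations. The statuses without effect came from the same kind of draws as the limits. Most of these outcomes follow from how the simulation was built, so they do not measure performance on the real lists.

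The named peaks were the 15 medium-only peaks with the highest score in each list, and the named windows the 5 with the most medium-only peaks, with ties at the fifth place counted together. This rule, the overlap, the score deciles, the draws and most alternatives were set before the data were examined. The analysis of peak numbers, the draws for windows, the rarity of single windows, and the alternatives for peak numbers and windows were added afterwards. The alternatives were an overlap of at least 50% of both peaks, a tolerance of 500 bp, the upper 50% of 1 or both lists by score (scores at or above the median, which includes the median peak of the odd-numbered normal-medium list), autosomes only, another medium-only peak within 50 kb in place of the nearest neighbour, peaks in either list of a medium, and each replicate left out. Planned results on promoters, exons and introns, on the CTCF motif and on gene lists were not run, since no genome sequence or gene annotation of hg19 was used here.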

Results

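CTCF, a zinc-finger DNA-binding protein that with cohesin anchors chromatin loops and domain boundaries, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in MCF7, an established oestrogen receptor-positive breast cancer cell line. Cells were kept either in normal medium or in medium lacking glucose. The title of the series concerns LATS, a kinase of the Hippo growth-control pathway, and a selective loss of CTCF from the genome, so the comparison asks which binding sites were called in one medium and not in the other. Each medium had 2 deposited peak lists, 4 in all. The 2 lists of normal medium were identical in all 11415 lines, and the 2 lists of glucose-free medium were identical in all 11338 lines. They therefore differed by less than any sampling noise and were counted as 1 sample per medium. No difference between the media below has a replicate check, and no p-value is given. Read depth is unknown, because the lists hold intervals and scores and no read counts. Positions refer to hg19, the build named in the submitters' processing notes. No gene annotation of that build was used here, so binding sites are named by position.

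The 2 media gave peak sets of nearly the same size. In normal medium 11415 peaks covered 21.6 Mb, and in glucose-free medium 11338 peaks covered 22.6 Mb. The median peak was 1755 bp wide in normal medium and 1851 bp in glucose-free medium. The highest score of both lists, 3100, belonged to an interval on chromosome 1 that began at position 121483571 in normal medium and at 121483097 in glucose-free medium. The interval ranked next in both lists lay on chromosome 2, from 739369 to 741448 in normal medium, with scores of 2305.84 and 2782.33. Scores are the peak caller's own and are used here mainly to rank peaks within a list. No peak was removed here for lying in repeats or other regions prone to mapping artefacts. A high score alone therefore does not show that an interval is a CTCF site.

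CTCF peaks were listed at mostly the same sites in both media. Of the normal-medium peaks, 9823 (86.1%, 95% exact binomial interval 85.4 to 86.7%) overlapped a glucose-free peak by at least 1 bp, and 1592 (13.9%, 13.3 to 14.6%) did not. Of the glucose-free peaks, 9819 (86.6%, 86.0 to 87.2%) overlapped a normal-medium peak, and 1519 (13.4%, 12.8 to 14.0%) did not. As a background, moving every peak by 100 kb left 3.00% of normal-medium peaks and 3.22% of glucose-free peaks overlapping the other list. The peaks found in 1 medium only were thus almost balanced, with 51.2% of them (49.4 to 52.9%) in normal medium. Shared peaks had a median score of 825.41 in normal medium and 920.08 in glucose-free medium. Since a score depends on library depth, which is unknown, the balance does not show that binding was equal. The intervals of the shares treat peaks as trials and cover counting error only, not the spread between cultures. Where 1 peak matched exactly 1 peak of the other medium, in 9806 pairs, the overlap covered a median of 98.6% of the normal-medium peak. In 6074 of these pairs (61.9%) the glucose-free peak was the wider, and over all pairs the median width difference was 48 bp, glucose-free minus normal. Medium-only peaks were not slightly displaced copies of listed peaks, since the median distance to the nearest peak of the other list was 51.5 kb for normal-only and 55.3 kb for glucose-free-only peaks. Only 47 normal-only and 60 glucose-free-only peaks lay within 5 kb of one.

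Sites with high-scoring peaks were listed in both media, and those listed in 1 medium only mostly had low scores. Among the lowest score decile of normal-medium peaks, 47.5% (44.6 to 50.5%) had no counterpart, against 0.175% (0.0212 to 0.632%), or 2 of 1141 peaks, in the highest decile. In glucose-free medium the lowest decile had 49.8% (46.9 to 52.8%) without counterpart and the highest had 0 of 1133 (exact interval up to 0.325%; 3 counts of the total, the limit used for a count of 0, are 0.265%). The lower 50% of each list by score held 1493 of the normal-only peaks (93.8%) and 1460 of the glucose-free-only peaks (96.1%). In the upper 50%, 99 of 5707 normal-medium peaks (1.73%, 1.41 to 2.11%) and 59 of 5669 glucose-free peaks (1.04%, 0.793 to 1.34%) were found in 1 medium only. In the upper 3 deciles these numbers were 28 and 9. A peak near the lowest listed score can be missed in 1 list by chance. The fall with score therefore does not by itself show an effect of the medium. Medium-only peaks were also narrower, with a median of 1510 bp against 1786 bp for shared peaks in normal medium, and 1674 bp against 1875 bp in glucose-free medium. The widths were not compared at equal score, so a difference apart from score is not shown.

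**Figure D1:**
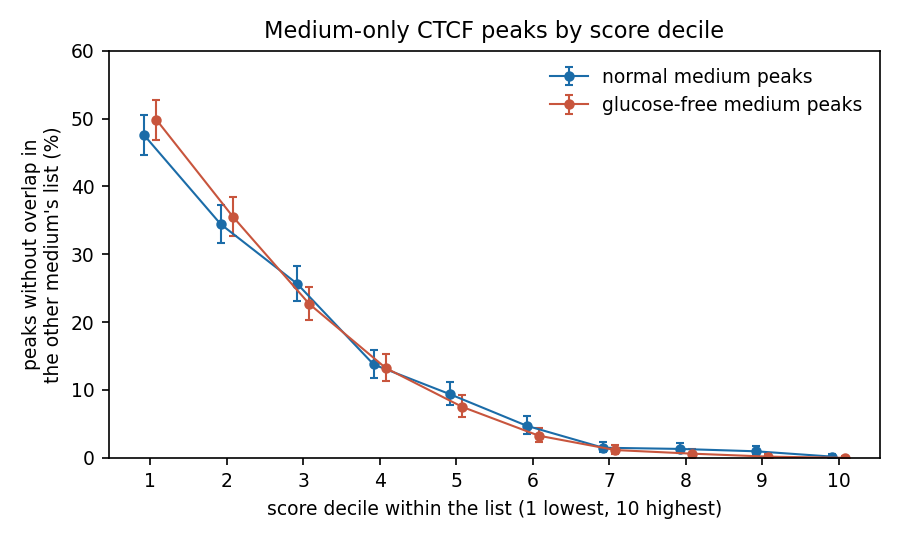
Percentage of CTCF peaks without an overlap in the other medium's list (y axis) in each score decile of the list (x axis, 1 lowest and 10 highest), for normal medium (blue) and glucose-free medium (red); bars are 95% exact binomial intervals. The share falls from 47.5% to 0.175% in normal medium and from 49.8% to 0% (interval up to 0.325%) in glucose-free medium.

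The lists used here had no line for some peak numbers, which bears on how a missing peak is read. Peaks carry running numbers in genome order. These reached 13511 in normal medium and 12991 in glucose-free medium, so that 2096 and 1653 numbers had no line, and the lowest listed scores were 514.21 and 512.01. A site found in 1 medium only was therefore checked for unlisted numbers between its listed neighbours in the other medium. For 767 of the 1592 normal-only peaks (48.2%, 45.7 to 50.7%) the glucose-free numbering left no number for a peak at any score. The same held for 513 of the 1519 glucose-free-only peaks (33.8%, 31.4 to 36.2%) in the normal-medium numbering. For the remaining 825 and 1006 peaks, a call that was left off the list could not be excluded. Several medium-only peaks can lie beside the same unlisted number. If each number stood for a call at no more than 1 of them, at least 895 normal-only and at least 620 glucose-free-only peaks had no call in the other medium. These counts and shares do not compare the media, because the normal-medium list lacked 2096 numbers and the glucose-free list 1653. A site without a call may still have carried enrichment below the caller's own threshold.

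Of the 15 strongest normal-only sites, 5 were on chromosome 19, more than on any other chromosome. The normal-only peak with the highest score, 1263.78, lay on chromosome 17 from 7759402 to 7762541, and the nearest glucose-free peak was 18.4 kb away. It was followed by a peak on chromosome 19 from 54972922 to 54976394 with a score of 1238.43. Next came a peak on chromosome 16 from 30102642 to 30104617 (score 1206.09) and one on chromosome 12 from 2921436 to 2922920 (score 1202.5). Besides those on chromosome 19, the 15 peaks lay 3 each on chromosomes 12 and 16, 2 on chromosome 1, and 1 each on chromosomes 15 and 17. The other chromosome 19 peaks of this group began at 40968896, 50378679, 47613818 and 46086674. Those on chromosome 12 also included the peaks from 53892476 to 53895981 and from 57080763 to 57084201. Those on chromosome 16 also included the peaks from 87810655 to 87813822 and from 87839439 to 87841647. The remaining 3 peaks were on chromosome 1, from 11968350 to 11969912 and from 228352522 to 228354811, and on chromosome 15 from 99663208 to 99665057. For 8 of the 15, including those named on chromosomes 12 and 17 and 4 of the 5 on chromosome 19, the glucose-free numbering left no number.

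The strongest glucose-free-only sites were spread over 10 chromosomes. The peak with the highest score, 1231.59, lay on chromosome X from 106241978 to 106243907, and the nearest normal-medium peak was 31.4 kb away. The next were on chromosome 13 from 52025429 to 52028474 (score 1224.81), chromosome 6 from 170861706 to 170864123 (score 1200.95) and chromosome 5 from 173314472 to 173316206 (score 1200.2). The remaining 11 had scores between 1029.01 and 1180.69. They included 3 peaks on chromosome 15, beginning at 69744203, 76602810 and 83875231, and 2 each on chromosomes 7 and 14, beginning at 32767293 and 155436080 and at 52455589 and 71274742. Single peaks lay on chromosome 4 from 152245459, on chromosome 1 from 181057117, on chromosome 6 from 168225880 and on chromosome 16 from 22200831. Of the 15, 3 had no number left in normal medium, on chromosomes 6 (from 170861706), 1 and 7 (from 155436080). The median distance to the nearest peak of the other medium was 60.5 kb for these 15 peaks and 27.4 kb for the 15 normal-only peaks.

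Chromosomes differed in which medium held the extra sites. On chromosome 19, 123 of 515 normal-medium peaks (23.9%, 20.3 to 27.8%) were normal-only, and on chromosome 17, 116 of 603 (19.2%, 16.2 to 22.6%). On chromosome X only 22 of 378 (5.82%, 3.68 to 8.68%) were, and on chromosome 18 only 13 of 160 (8.13%, 4.40 to 13.5%). Glucose-free-only peaks made up 66 of 458 (14.4%, 11.3 to 17.97%) on chromosome 19, close to the 13.4% of the whole list, and 51 of 538 (9.48%, 7.14 to 12.3%) on chromosome 17. They made up 70 of 426 (16.4%, 13.0 to 20.3%) on chromosome X and 35 of 182 (19.2%, 13.8 to 25.7%) on chromosome 18. Normal-only peaks were thus 69.5% (61.9 to 76.3%) of all medium-only peaks on chromosome 17 and 65.1% (57.8 to 71.9%) on chromosome 19. They were 23.9% (15.6 to 33.9%) on chromosome X and 27.1% (15.3 to 41.8%) on chromosome 18. Chromosome 9 leaned the same way as chromosome 17, with 62.0% (53.1 to 70.4%), whereas chromosome 11 had 79 peaks in each group. On chromosomes 20, 21 and 22 both kinds were frequent. Normal-only peaks made up 19.7, 19.2 and 20.3% of the normal-medium peaks there, and glucose-free-only peaks 18.6, 21.5 and 22.3% of the glucose-free peaks.

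Peaks also differ in score between chromosomes, so the counts on chromosomes 17, 18, 19 and X were set against draws matched on score. When medium-only status was redrawn 10000 times within score deciles, a median of 86 normal-only peaks fell on chromosome 19 (95% range 71 to 101) and no draw reached 123. On chromosome 17 the median was 87 (72 to 102) and 1 draw reached 116. On chromosome X the draws gave 48 (37 to 60), and none was as low as 22. For glucose-free-only peaks, chromosomes 17 and 19 lay below their ranges of 60 to 87 and 75 to 105. Chromosomes 18 and X lay above theirs, of 17 to 33 and 45 to 69. In all, 7 of the 23 chromosomes with at least 10 peaks lay outside the 95% range in normal medium and 4 in glucose-free medium, where the draws themselves give about 1 in 20. The other 3 in normal medium were chromosomes 8 and 20, with more normal-only peaks than drawn (82 and 62), and chromosome 2 with fewer (82 against a median of 104). The draws treat peaks as independent. Normal-only peaks tended to lie next to each other, as described below, so the ranges for normal medium may be too narrow and the rate of 1 in 20 too low. Chromosome 9 lay within its ranges in both lists, with 80 normal-only peaks (57 to 84) and 49 glucose-free-only peaks (47 to 72). Among the upper 50% of normal-medium peaks by score, chromosome 19 still held 23 normal-only peaks out of 201 (11.4%, 7.39 to 16.7%). Chromosome 17 held 9 of 289 there (3.11%, 1.43 to 5.83%) and chromosome 18 held 0 of 79 (exact interval up to 4.56%), both within the range of the draws, as were chromosomes 2, 8 and 20. The 5 chromosomes outside the draws there were 16 and 19 above and 4, 6 and X below, the latter with 0 of 248, 0 of 312 and 0 of 207 peaks (exact intervals up to 1.48, 1.18 and 1.77%). For glucose-free-only peaks of the upper 50%, none of chromosomes 17 (0.386%), 18 (2.11%), 19 (0.826%) and X (1.87%) lay outside the draws, and chromosome 22 (7.27%) did. With an overlap of 50% of both peaks required, chromosomes 18 (9.38%) and 20 (20.3%) for normal-only peaks and chromosome X for glucose-free-only peaks (17.1%) also came within the range, which left 5 and 3 chromosomes outside.

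**Figure D2:**
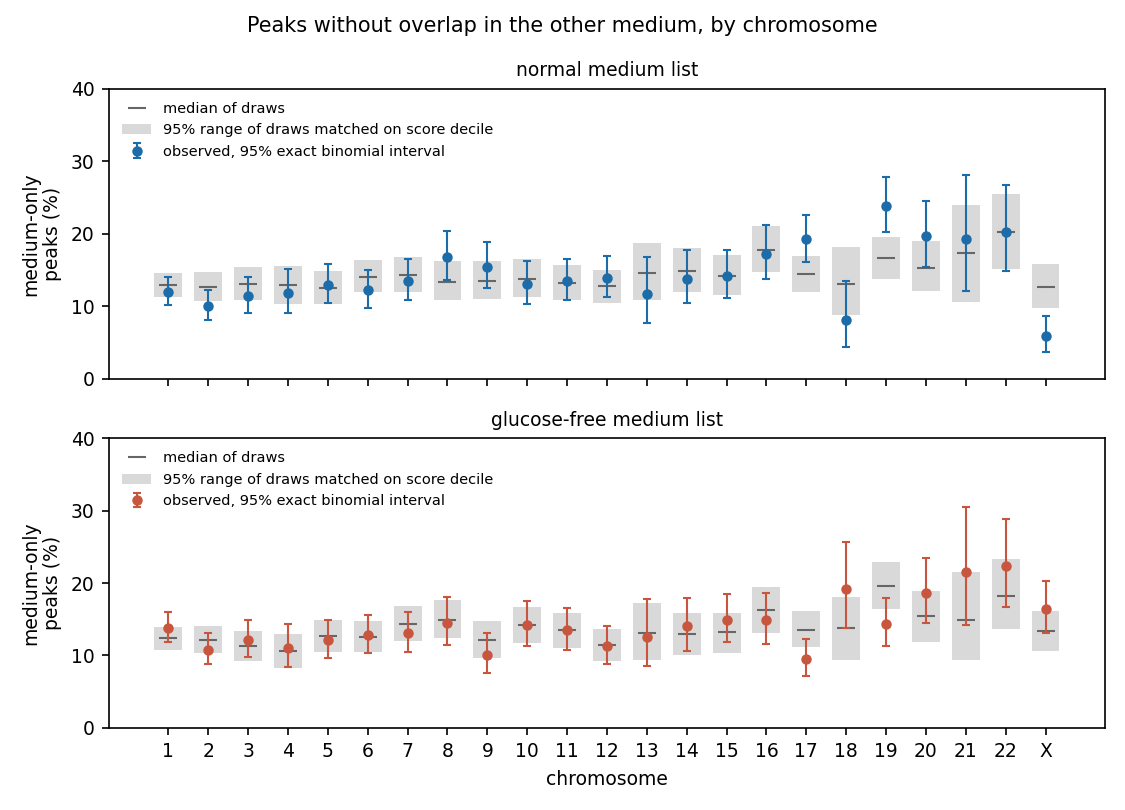
Percentage of CTCF peaks without an overlap in the other medium (y axis) on each chromosome (x axis) for the normal-medium list (upper panel) and the glucose-free list (lower panel). Points are observed shares with 95% exact binomial intervals, and grey bars and ticks are the 95% range and median of 10000 draws matched on score; chromosomes 17 and 19 lie above the bars for normal medium (19.2% and 23.9%) and below them for glucose-free medium (9.48% and 14.4%).

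Normal-only sites tended to lie next to each other. For 363 of the 1592 normal-only peaks (22.8%), the nearest peak of the same list was also normal-only, against a median of 15.8% (95% range 13.7 to 17.9%) in 10000 draws matched on score decile and chromosome, none of which was as high. For glucose-free-only peaks the share was 17.1%, within the range of its draws (13.3 to 17.4%). Whether the 2 media differ in this respect was not tested. Among the upper 50% of normal-medium peaks by score, which holds 99 normal-only peaks, the share was 7.07% and lay within the range of its draws.

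The 1 Mb windows with the most normal-only peaks had 8 each, on chromosome 19 from 36 to 37 Mb, chromosome 11 from 64 to 65 Mb and chromosome 17 from 73 to 74 Mb. These windows also held 12, 13 and 22 shared peaks, and 0, 1 and 0 glucose-free-only peaks. A further 6 windows had 7 normal-only peaks, with 3 of them on chromosome 19 (from 40 to 41, 41 to 42 and 46 to 47 Mb). The others were on chromosome 16 from 2 to 3 Mb, chromosome 20 from 62 to 63 Mb and chromosome 8 from 128 to 129 Mb. In the chromosome 8 window 7 of the 8 normal-medium peaks were normal-only, and in the chromosome 20 window 7 of 10. The windows with the most glucose-free-only peaks had 6 each, on chromosome 5 from 177 to 178 Mb, chromosome 6 from 26 to 27 and from 43 to 44 Mb, and chromosome 7 from 99 to 100 Mb, and a further 8 windows had 5. The highest count of a draw had a 95% range of 6 to 9 for normal-only and 5 to 9 for glucose-free-only peaks, so neither highest count exceeded that of random placement.

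**Figure D3:**
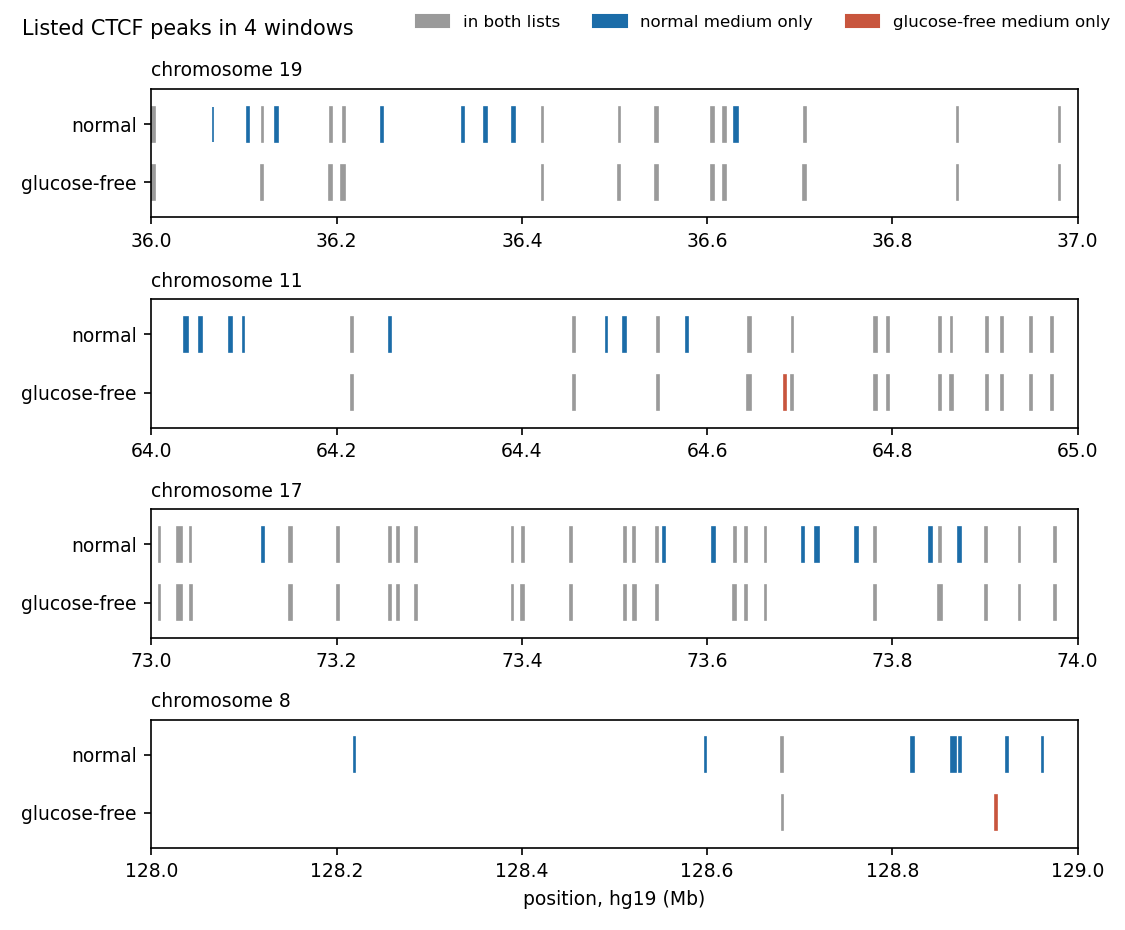
Listed CTCF peaks along 4 windows of 1 Mb (x axis, hg19 position in Mb) in normal medium (upper row of each panel) and glucose-free medium (lower row), drawn to scale; grey peaks overlap a peak of the other medium, blue peaks are normal-only and red peaks glucose-free-only. The windows on chromosomes 19, 11 and 17 hold 8 normal-only peaks each, and the window on chromosome 8 holds 7 beside 1 shared peak.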

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

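No p-value depends on these settings, and the values describe 2 lists. Apart from the settings on identical lists, 100 values were recomputed under alternatives. Of these, 68 stayed on the same side of their range or within the stated limit. Another 23 moved beyond it and 9 came within the range of the draws. A reversed direction could be recorded only for the shares of single chromosomes and of neighbours set against draws, and none occurred. Some outcomes were fixed in advance. With the autosomes alone the shares of chromosomes 17, 18 and 19 could not change, and the upper 50% of a list must hold fewer peaks. The tally is therefore not a measure of stability. Leaving out replicate 1 or 2, joining the lists of a medium, and the replicate block (1 with 1, 2 with 2) all gave 1592 normal-only and 1519 glucose-free-only peaks, because the lists of a medium are identical; this says nothing about stability between cultures. Requiring an overlap of 50% of both peaks gave medium-only shares of 15.0% (normal) and 14.4% (glucose-free), of 27.7% and 27.1% in the lower 50% of the lists by score and of 2.37% and 1.78% in the upper 50%. The upper 50% by score, here with the median peak included, held 5708 normal-medium peaks over 11.5 Mb and 5669 glucose-free peaks over 11.8 Mb. Matched against the whole other list, it left 99 normal-only (1.73%) and 59 glucose-free-only peaks (1.04%), of which 40 and 16 had no number left in the other list. Matched against the upper 50% of the other list, it left 975 (17.1%) and 936 (16.5%), since sites then fall out by rank in either list. With the upper 50% against the whole other list, 5 chromosomes in place of 7 lay outside the draws for normal-only peaks, only 19 and X among the earlier 7, and 1 in place of 4 for glucose-free-only peaks, none of the earlier 4; the share of normal-only peaks with a normal-only neighbour fell to 7.07% and came within its draws, with fewer peaks tested. A tolerance of 500 bp and the autosomes alone moved none of the counts of medium-only peaks by over 1.5 times. Another medium-only peak within 50 kb was found for 18.3% of normal-only peaks (draws 10.5 to 14.6%) and 12.4% of glucose-free-only peaks (draws 9.08 to 13.2%). The planned results on genomic position, the CTCF motif and the gene lists were not run. Depth is unknown, so how many of the medium-only peaks a deeper library would recover was not tested.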

Other observations

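The test of peak density, that of shared ranks over both pairs of chromosomes and that of the flanks of the chromosome 8 window were set before their results were seen, and the other tests of this part were chosen afterwards. The sites shared by both media also changed places in the ranking by score on some chromosomes. The 9806 shared pairs were ranked within each list, and the shift of each site from normal to glucose-free medium was taken. On chromosome 19 the median of these shifts was -7.57 percentile points (95% bootstrap interval -9.56 to -5.16, 392 pairs), the lowest of any chromosome. The median shift was 4.40 points (1.36 to 7.33, 147 pairs) on chromosome 18 and 6.14 points over 84 pairs on chromosome 21. Chromosomes 4 and 13 had shifts of 2.77 and 2.93 points. Most other chromosomes stayed within 2 points, among them chromosome 1 with 0.497 over 1002 pairs. Genes and sites of 1 library are not replicates, and these intervals cover the spread between sites only.

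Medium-only peaks lay mostly near the lowest listed scores, and a candidate explanation is that they were called in the other medium and left off its list. This cannot account for all of them, since 48.2% of normal-only and 33.8% of glucose-free-only peaks had no number left there. For the others it remains open, and intervals that held medium-only peaks had unlisted numbers more often than those that held none. Intervals between listed glucose-free peaks had unlisted numbers in 48.9% of cases when they held a normal-only peak, against 12.4% for intervals of matched length that held none, a ratio of 3.96 (3.62 to 4.32). In the normal-medium list the shares were 62.6% and 14.2%, a ratio of 4.40 (4.07 to 4.76). An unlisted number has no position, and the intervals were matched on length alone. The ratios therefore do not show that the unlisted calls lay at the medium-only sites.

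Set against draws matched on score, chromosomes 17 and 19 had more normal-only and fewer glucose-free-only peaks, and X and 18 the reverse. On X the glucose-free-only peaks barely passed their range (70 against 45 to 69), while normal-only peaks were few (22 against 37 to 60). By raw share, chromosomes 20 and 22 exceeded chromosome 17 for normal-only peaks, and 20, 21 and 22 exceeded X for glucose-free-only peaks. A library difference that follows peak density was examined as a cause of the pattern on chromosomes 17, 18, 19 and X. Outside these 4 chromosomes the values argue against it. Normal-only peaks there were 50.4% of medium-only peaks in the densest windows and 52.7% in the sparsest, a difference of -2.22 points (-6.95 to 2.504). Over all chromosomes, those of the pattern included, the shares were 53.2% and 49.8%, a difference of 3.37 points (-1.21 to 7.96). For the chromosomes of the pattern the test cannot decide, because it left them out. Its intervals also treat neighbouring peaks as independent. A difference over whole chromosomes that includes the shared peaks, as base composition or copy number could give, is consistent with the shift of shared ranks by -3.78 points (-5.10 to -2.65) on chromosomes 17 and 19 together and 2.34 points (0.551 to 3.87) on X and 18. This rests on chromosomes 19 and 18, since chromosome 17 alone shifted by -0.984 points (-2.59 to 0.449) and X alone by 1.53 (-0.319 to 3.33), where the intervals are too wide to decide. Elsewhere shift and share went together only in part. Chromosomes 21, 13 and 4, with shifts of 6.14, 2.93 and 2.77 points, had normal-only parts of 46.5% (31.2 to 62.3%), 48.1% (34.0 to 62.4%) and 51.9% (41.97 to 61.7%) of their medium-only peaks, intervals too wide to show a mismatch. Chromosome 9, with 62.0% (53.1 to 70.4%), shifted by 0.229 points. On the remaining chromosomes except 11 and 15, a negative shift went with more normal-only than glucose-free-only peaks, and a positive shift with fewer. The intervals of these shares all included an equal split. Chromosome Y, with 3 shared pairs, was left out. A response of binding to glucose-free medium stays open as well and cannot be told apart from a difference between libraries, because each medium has only 1 distinct list.

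In the window of chromosome 8 from 128 to 129 Mb, 7 of 8 normal-medium peaks were normal-only, where draws matched on score gave a median of 2 (0 to 4) and 1 of 10000 reached 7. Low scores of the peaks, with every 1 Mb window searched, remain a possible explanation, since 7% of draws had some window as rare among the 2352 windows. A change over a block of several Mb, such as a copy-number difference, cannot be told apart either. In the 2 Mb on either side, 5 of 16 peaks were normal-only (31.3%, 11.02 to 58.7%), too few to decide. Each of the 7 normal-only peaks of the window had 1 or 2 unlisted glucose-free numbers between its listed neighbours. A call left off the glucose-free list was therefore not excluded for any single one of them, though several may lie beside the same number. In all, 4 windows had a normal-only count seen in at most 0.1% of draws, where the draws themselves gave 0 to 2 such windows. These draws were not matched on chromosome. On chromosome 19, which held more normal-only peaks than drawn, the windows from 36 to 37 Mb and from 46 to 47 Mb had counts reached in 5 and 3 of 10000 draws. The excess of such windows may therefore in part repeat that of chromosome 19.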
